A study of Danio rerio with 4 samples.

How the data were processed

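Total RNA from pooled zebrafish larvae collected 120 h after fertilisation was sequenced after removal of ribosomal RNA, and each library was summarised as reads per gene and reads per repeat family. The labels describe pools of 10 to 20 entire larvae from 2 clutches, sorted by appearance into uhrf1 mutants and normal-looking siblings, with 1000 ng of RNA per library and 75 bp reads from a single end. There were 2 mutant and 2 sibling libraries. The labels do not tie a replicate number to a clutch, so the p-values measure the spread between these libraries.

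The gene and repeat values are raw read counts that the authors deposited with 1 column per library, per the file headers. The sibling columns are headed ABNYU and the mutant columns are not. Whether this name marks another origin was not tested. TopHat2, HTSeq and DESeq2 and the genome build GRCz10 are named without versions, per the submitters' processing notes. The settings, the handling of reads that map to several places, the use of strand and the repeat annotation are not given in the sources used here. Repeat families have many near-identical copies, so a repeat count depends on how such reads were assigned. The same holds for close paralogs among the genes, such as the myhz1 myosins, the crystallins, the prss59 trypsins and the c3 complement genes. Reads of overlapping or antisense genes cannot be separated without strand.

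The gene table held 31953 Ensembl identifiers, of which 26121 were matched to a symbol, and the repeat table held 11258 names. Some symbols are written in the capitals of human genes and were kept that way. Genomic positions were not analysed here. Gene reads per library were 571978 and 564941 for the mutants and 613370 and 812167 for the siblings. Repeat reads were 9671737 and 10559130 for the mutants and 2108906 and 1611818 for the siblings. At this depth a count of 0 allows up to 3.25 and 3.22 CPM (read counts relative to the scaled gene reads of the library) in the mutant libraries and 8.11 and 8.28 in the sibling libraries, taking 3 counts as the floor. Such floors, and the Wilson 95% intervals given for shares of reads, cover counting error only.

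Genes were tested with the quasi-likelihood test of edgeR 4.0.16 (robust fit, R 4.3.3) after its default count filter by group and TMM scaling, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Repeat families were tested in the same way, but library sizes and TMM factors came from the gene counts of the same library, so that a shift of all repeats stays visible. The CPM of repeats are therefore also relative to scaled gene reads. The TMM factors were 1.78 and 1.83 for the mutants and 0.63 and 0.485 for the siblings. Repeat names were sorted into classes by their spelling after the data had been examined. Fold changes are mutant over sibling on the log2 scale, and ± after a log2 fold change is its standard error with n = 2 libraries per group. Where a group had 0 counts in both libraries, the fold is a lower bound against 3 counts over the group.

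Gene lists were fixed before the data were examined: 23 lists of pathways and of markers of the tissues a larva holds. Lists with at least 5 tested members, and repeat classes with at least 10 tested families, were compared with all other tested genes or families by camera in limma 3.58.1, with a preset correlation of 0.01 and a prior count of 2. The camera test with an estimated correlation, which has few residual degrees of freedom here, and fry, which asks whether a set moves on balance in a given direction, were run beside it. Genes were named by a rule fixed at the same time. It takes uhrf1 and dnmt1, the 6 largest changes in each direction among genes past the threshold with a mean of at least 5 CPM, separate groups and a proper symbol, and up to 3 members per list by smallest p. For repeats it takes the 5 largest changes in each direction and the families with the smallest p in each class. Some genes that this rule takes are not reported here. Other genes named were chosen after their values were seen, and are said to be so.

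On simulated counts with the real library sizes, 2.47% of genes changed 2-fold were recovered among 6533 tested, 71.2% of those changed 4-fold among 6673 and 98.3% of those changed 16-fold among 7612, with 0, 1 and 15 false calls. For repeat families the shares were 15.9% among 3314, 88.4% among 3291 and 99.5% among 3284, with 2, 6 and 5 false calls. An interferon list changed 2-fold in simulated counts had an adjusted p of 4.83e-10 by camera among 21 lists, and 0 other lists were called. Both simulated groups came from the same pooled profile with a single dispersion of 0.066, and each gene was drawn independently. The real groups differed in spread and in most tested genes, so these rates and this p-value may not carry over.

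Replicates were compared before use. The chi-square statistic per degree of freedom over genes was 1.31 for the mutant pair and 35.5 for the sibling pair. Over repeat families it was 8.52 and 62.9. Each library was counted once, although 1.31 is near counting error and does not tell separate pools from repeat sequencing of the same pool. Both groups share a dispersion per gene in the fit, so standard errors and p-values may understate the spread of the siblings. With 2 libraries against 2, an exact two-sided permutation test of a single value cannot go below p = 0.333. Alternatives were other scalings, other count filters, DESeq2 1.42.0, a replicate block, a minimum fold of 1.5 tested with glmTreat, and leaving out each library in turn. When a library is left out, the lone library of its group is assumed to vary like the other group. Scaling to 79 ribosomal protein genes, total-count scaling of the lists, and the leave-one-out values of the ratio of repeat to gene reads were added after seeing the data. Figures were drawn with matplotlib 3.10.9.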

Results

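Per the labels, the libraries compare zebrafish larvae that carry the hi272 mutation in uhrf1 with their normal-looking siblings at 5 days of age. Uhrf1 is a chromatin protein that brings the maintenance DNA methyltransferase Dnmt1 to newly replicated DNA. The question was how transcripts of genes and of repeats differ between mutants and siblings. Each group had 2 libraries, and the labels describe all 4 as pools of whole larvae. The mutant libraries held 571978 and 564941 gene reads and the sibling libraries 613370 and 812167. With these depths, 21018 and 21135 genes had a read in the mutant libraries, and 14160 and 14397 genes had a read in the sibling libraries.

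UHRF1 (ENSDARG00000103409), the mutated gene, had 7 and 9 reads in the mutant libraries and 2 and 17 in the sibling libraries. These are 8.63 ± 1.46 CPM and 26.2 ± 29.4 CPM (mean ± SD, n = 2), and the gene did not pass the count filter. Without the filter its log2 fold change was -1.24 ± 0.95 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.432), so its reads do not check the labels at this depth. DNMT1 (ENSDARG00000030756), the maintenance methyltransferase, had 58 and 73 reads in the mutants and 4 and 14 in the siblings. It rose by 1.51 ± 0.46 on the log2 scale (edgeR, Benjamini-Hochberg adjusted p = 0.0125), and without the count filter its adjusted p was 0.108.

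Liver transcripts fell and transcripts of muscle, eye, nerve, cartilage and skin rose in the mutant libraries relative to the libraries labelled sibling. Tissue makeup and genotype coincide here, so fell and rose describe the libraries and do not assign a change to the mutation. Hepatocyte markers took 0.241% (Wilson 95% interval 0.229% to 0.254%) and 0.153% (0.143% to 0.164%) of gene reads in the mutants. In the siblings they took 19.9% (19.8% to 20.0%) and 15.7% (15.6% to 15.8%). Skeletal muscle markers took 6.51% (6.45% to 6.58%) and 5.91% (5.85% to 5.97%) in the mutants and 0.253% (0.240% to 0.266%) and 0.157% (0.149% to 0.166%) in the siblings. Lens markers had 881 and 1217 reads in the mutants and 3 and 4 in the siblings. Of 8133 genes tested, 2861 were higher and 2104 lower in mutants, and 1323 and 766 of these changed at least 10-fold (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). The median of all tested genes was 0.48 on the log2 scale. With total-count scaling the median was 2.17 and the split 5585 higher and 1015 lower. With ribosomal protein scaling, added after seeing the data, the median was 3.13 and the split 6444 higher and 650 lower. Leaving out mutant replicate 1 gave 1264 changed genes and leaving out mutant replicate 2 gave 1981, against 4965 with all libraries. With no count filter 3002 genes changed.

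**Figure D1:**
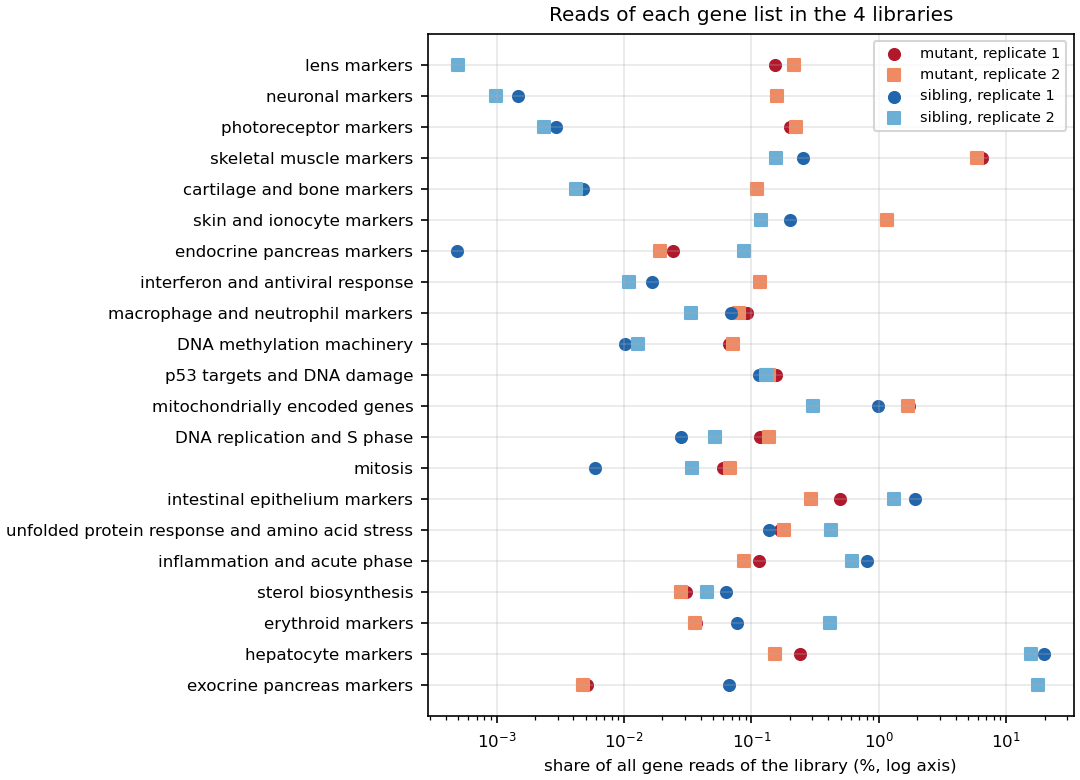
Share of all gene reads of a library, in percent on a log axis, taken by each gene list with at least 5 tested members. Each point is 1 library, with red for mutants and blue for siblings, and circles for replicate 1 and squares for replicate 2. Hepatocyte markers reach 19.9% and 15.7% in the siblings, and exocrine pancreas markers reach 17.7% in sibling replicate 2 alone.

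The genes with the largest fitted increases had no read in either sibling library, so their order depends on the prior count and their folds are given as lower bounds. Genes with sibling reads, such as the myosin myhz1.1 with a fitted 199-fold, can exceed these bounds. MYL11 (ENSDARG00000002589), a myosin light chain of fast muscle, had 404 and 389 reads in mutants and was at least 104-fold higher. Parvalbumin pvalb3 was at least 83.6-fold higher. The collagens COL11A1 and col17a1a were at least 65.6-fold and 62.0-fold higher, and the cone opsin OPN1SW at least 52.4-fold higher. The largest decreases were in genes of liver and digestive tract. RBP2 (ENSDARG00000093774), a retinol-binding protein, had 0 reads in both mutants and 727 and 630 in the siblings, at least 1145-fold lower. The plasma protein genes itih3a.1, ahsg1 and habp2 were at least 741-fold, 711-fold and 540-fold lower, and rnasel2 at least 642-fold lower. The C-reactive protein gene crp5 had 0 and 1 reads in mutants and 1449 and 1061 in siblings. Adjusted p for these genes lay between 4.03e-08 and 5.25e-05 (edgeR quasi-likelihood test, Benjamini-Hochberg).

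All 41 tested hepatocyte markers fell, with a median log2 fold change of -7.50 (camera adjusted p = 7.28e-22; adjusted p = 0.34 with an estimated correlation). The carboxylesterase ces3, ambp and the cytochrome P450 cyp2ad2 fell, with log2 fold changes of -9.90 ± 0.51, -9.10 ± 0.49 and -8.64 ± 0.47. Exocrine pancreas markers, which encode digestive enzymes, had 29 and 27 reads in the mutants, 407 in sibling replicate 1 and 143622 in sibling replicate 2. Of 11 tested, 2 fell and 9 did not pass, with a median of -12.55 (camera adjusted p = 0.00347; adjusted p = 0.558 with an estimated correlation). The amylase amy2al1 was at least 84.4-fold lower and PLA2G1B, a phospholipase, fell by 10.55 ± 2.37. The trypsin gene prss59.2 had 5 and 6 reads in mutants against 57 and 39655 in siblings. Over the exocrine markers tested in each fit, the median was -13.43 without sibling replicate 1 and -4.63 without sibling replicate 2. It was -12.08 and -12.05 without mutant replicate 1 and 2. A fit with a lone sibling library takes its spread from the mutant pair and leaves out the difference between the siblings. Of the intestinal markers, 7 of 12 fell and 2 rose, with a median of -1.21 (camera adjusted p = 0.0244; adjusted p = 0.448 with an estimated correlation), against 5 lower and 4 higher with total-count scaling (median 0.46) and 4 lower and 6 higher with ribosomal protein scaling (median 1.41). The lipid transfer gene MTTP, apoa4b.1 and PKLR, which the liver also uses, fell, with log2 fold changes of -4.67 ± 0.35, -5.27 ± 0.40 and -7.01 ± 0.58. Erythroid markers fell in 6 of 10 tested genes, with a median of -3.12 (camera adjusted p = 0.00843; adjusted p = 0.34 with an estimated correlation). With total-count scaling 3 rose and 5 fell (median -1.44), and with ribosomal protein scaling 3 rose and 3 fell (median -0.49). Among them the globin hbae5, the carbonic anhydrase cahz and RHAG were at -7.07 ± 0.51, -4.12 ± 0.48 and -2.84 ± 0.35.

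Photoreceptor markers rose in 18 of 18 tested genes, with a median of 6.47, or 3.92 with genes at 0 in siblings set to their bound (camera adjusted p = 1.68e-06; adjusted p = 0.34 with an estimated correlation). The red opsin opn1lw2 was at least 29.6-fold and the cone transducin GNAT2 at least 25.9-fold higher. Lens markers rose in 18 of 18, with a median of 8.05, or 3.64 with bounds (camera adjusted p = 2.13e-06; adjusted p = 0.448 with an estimated correlation). The crystallins crybb1l1, CRYBB1 and crybb1l2 were at least 36.2-fold, 35.7-fold and 21.3-fold higher. Neuronal markers rose in 14 of 14, with a median of 6.70, or 3.78 with bounds (camera adjusted p = 4.13e-05; adjusted p = 0.34 with an estimated correlation). The RNA-binding gene ELAVL4 was at least 27.5-fold higher, and the synaptic vesicle gene SV2A rose by 6.44 ± 0.66. Cartilage and bone markers rose in 8 of 9, with a median of 5.95, or 3.61 with bounds (camera adjusted p = 0.00274; adjusted p = 0.34 with an estimated correlation). COL11A2 was at least 17.9-fold higher, col11a1b rose by 5.95 ± 0.54 and MATN4 by 5.06 ± 0.65. Without mutant replicate 1 the numbers that rose were 9 photoreceptor, 9 lens, 6 neuronal and 2 cartilage genes, and without mutant replicate 2 they were 10, 12, 9 and 6.

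Skeletal muscle markers rose in 19 of 24 tested genes and fell in 1, with a median of 6.02, or 5.92 with bounds (camera adjusted p = 4.13e-05; adjusted p = 0.34 with an estimated correlation). The fast myosin myhz1.3 had 2157 and 1876 reads in mutants and 1 and 2 in siblings, a rise of 8.99 ± 0.52. The related myhz1.1 rose by 7.64 ± 0.47 and pvalb2 by 6.83 ± 0.43. The gene that fell was ENO3, named after its value was seen, an enolase that fell by 4.08 ± 0.37. Skin and ionocyte markers rose in 19 of 25 and fell in 3, with a median of 3.13, or 2.75 with bounds (camera adjusted p = 0.00542; adjusted p = 0.409 with an estimated correlation). The keratins krt5 and cyt1 rose by 6.95 ± 0.48 and 6.21 ± 0.49. The 3 that fell, named after their values were seen, were the keratins krt94, krt8 and krt92, at -3.28, -2.46 and -2.02. With total-count scaling only krt94 fell (-1.59), and with ribosomal protein scaling none of the 3 passed and they were at -0.64, 0.17 and 0.61. The number of skin genes that rose was 9 without mutant replicate 1, and without mutant replicate 2 there were 12. Pancreatic islet markers rose in 3 of 5 tested genes, the prohormone convertase PCSK1 by 3.33 ± 0.81, NEUROD1 by 2.55 ± 0.73 and ISL1 by 2.44 ± 0.84, with a median of 2.44 (camera adjusted p = 0.303). Other members passed the count filter when a library was left out, and the list median was then -6.02 without sibling replicate 1 (6 of 11 lower, 0 higher). It was -4.84 and -5.22 without mutant replicate 1 and 2, where 0 members passed, and 7.31 without sibling replicate 2, where 5 of 5 rose. These 3 genes are also active in neurons, and the islet list held 3 reads in sibling replicate 1 and 713 in sibling replicate 2.

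**Figure D2:**
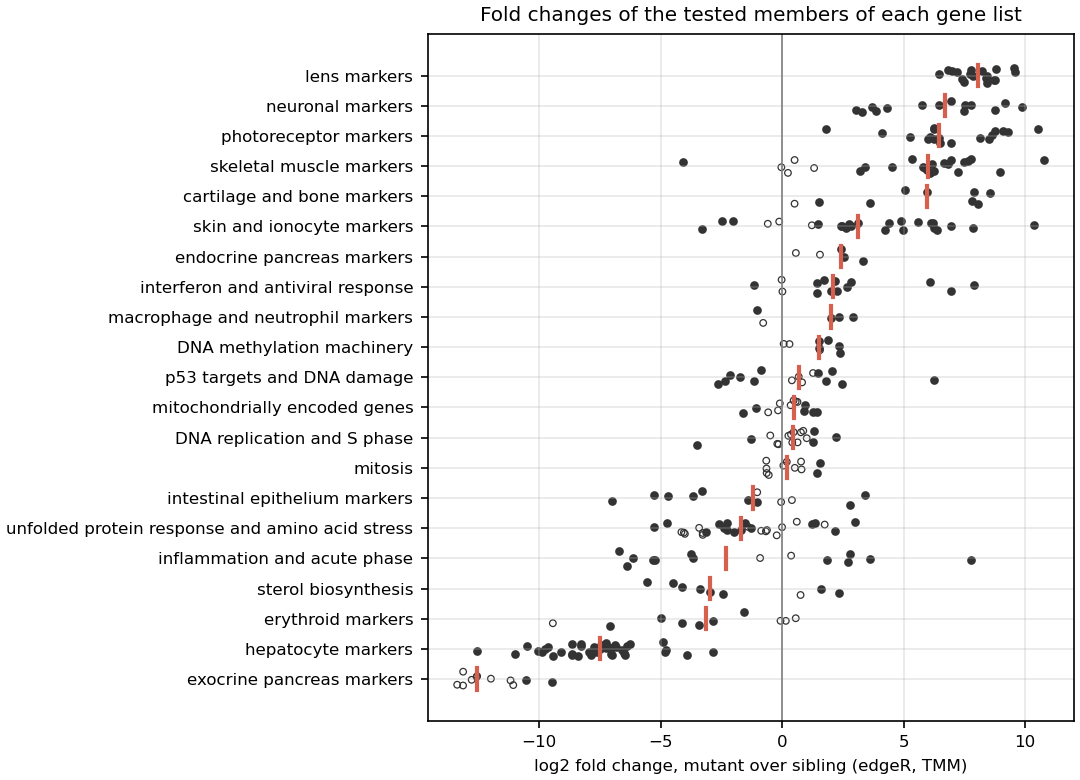
Log2 fold change of each tested list member, mutant over sibling (horizontal axis), by gene list (vertical axis). Filled points passed the threshold of adjusted p under 0.05, open points did not, and the red bar is the list median, which runs from -12.55 for exocrine pancreas to 8.05 for lens. Medians of the intestinal, unfolded protein response and inflammation lists turn positive under ribosomal protein scaling.

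Interferon and antiviral genes rose in 11 of 14 tested members and fell in 1, with a median of 2.09, or 1.87 with bounds (camera adjusted p = 0.0166; adjusted p = 0.34 with an estimated correlation). The antiviral GTPase mxc had 44 and 41 reads in mutants and 0 in siblings, at least 11.2-fold higher. The class I antigen subunit b2m rose by 2.68 ± 0.49 and parp14rs1 by 2.83 ± 0.53. The gene that fell was trim25, named after its value was seen, at -1.14 ± 0.43, but it was at 0.55 with total-count scaling and rose with ribosomal protein scaling (adjusted p = 0.0144). In all, 13 of 14 members rose with the former and 14 of 14 with the latter, where 5585 and 6444 of all 8133 tested genes rose. Without mutant replicate 1 only 1 member passed, without mutant replicate 2 there were 4, and without sibling replicate 1 there were 6. This rise stood beside the rise of muscle, eye, nerve and skin markers in the same libraries. Macrophage and neutrophil markers rose in 3 of 5 tested genes and fell in 1, with a median of 1.99 (camera adjusted p = 0.83). The antigen presentation genes cd74a and cd74b rose by 1.99 ± 0.46 and 2.34 ± 0.72 and the receptor csf1ra by 2.93 ± 0.82, and the apolipoprotein apoeb, named after its value was seen, fell by 1.04 ± 0.32. It was at 0.63 with total-count scaling and rose, at 1.57, with ribosomal protein scaling, where 5 of 5 members rose. The T cell and thymus genes bcl11ba, TOX and GATA3, which neurons and other tissues also use, were at least 8.16-fold, 6.32-fold and 3.95-fold higher, and this list had too few tested members for camera. Macrophage and neutrophil genes that rose numbered 0 without either mutant library, 1 without sibling replicate 1 and 2 without sibling replicate 2, and 1 fell without mutant replicate 2 and 3 without sibling replicate 2. T cell genes that rose numbered 0 without mutant replicate 1, 2 without mutant replicate 2 and 1 without sibling replicate 1.

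Of 14 inflammation and acute phase genes 5 were higher and 7 lower, with a median of -2.29 (camera adjusted p = 0.124) that was 0.39 with ribosomal protein scaling, where 7 were higher and 6 lower. The complement genes c3b.2, cfb and c3a.3, made mainly in liver, fell, at -6.40 ± 0.45, -6.15 ± 0.46 and -5.31 ± 0.40, beside the fall of the hepatocyte markers. The number of inflammation genes that rose was 0 without mutant replicate 1 and 2 without mutant replicate 2, and 6 and 7 fell. Genes of the DNA methylation machinery rose in 5 of 8 tested and fell in 0, with a median of 1.54 (camera adjusted p = 0.279), and 8 of 8 rose with total-count or ribosomal protein scaling. In those scalings 5585 and 6444 of all 8133 tested genes rose. The demethylation enzyme TET2 rose from 12.3 ± 1.75 CPM in siblings to 65.8 ± 11.7 CPM in mutants (mean ± SD, n = 2). The related tet3 rose by 2.33 ± 0.70 and the methyltransferase dnmt3ba by 1.91 ± 0.56 on the log2 scale. Without mutant replicate 1 or mutant replicate 2, 1 methylation gene rose, and without sibling replicate 1, 2 rose and 1 fell.

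Of 15 p53 targets 5 were higher and 6 lower, with a median of 0.69 where camera gave the opposite direction (adjusted p = 0.853). With total-count scaling 9 were higher and 0 lower (median 2.39), and with ribosomal protein scaling 11 and 0 (median 3.35). For comparison with these and the next 2 lists, the medians of all tested genes were 2.17 and 3.13 in these scalings. The proapoptotic bbc3 was at least 3.55-fold higher. CCNG1 and rps27l fell, at -2.33 ± 0.38 and -2.16 ± 0.36, but under ribosomal protein scaling they were at 0.39 and 0.54. No p53 target passed without mutant replicate 1, without mutant replicate 2 only 1 did, and without sibling replicate 1 there were 3 in each direction. In S phase genes 3 of 16 rose and 2 fell (median 0.45, camera adjusted p = 0.811), with RRM2 lower by a log2 fold change of -3.51 ± 0.60 and MCM4 and chaf1a higher by 1.29 ± 0.38 and 2.23 ± 0.66. With total-count scaling 14 S phase genes were higher and 1 lower (median 2.16), and with ribosomal protein scaling 15 and 0 (median 3.13). Of 11 mitosis genes, CENPF and ASPM rose by 1.56 ± 0.61 and 1.43 ± 0.59 (list median 0.19, camera adjusted p = 0.82), and 0 passed when adjusted over the list alone. With total-count scaling 7 of 11 mitosis genes were higher (median 1.90), and with ribosomal protein scaling 11 of 11 (median 2.86). Mitosis calls numbered 0 without either mutant library, 4 genes fell and 0 rose without sibling replicate 1, and 5 rose and 0 fell without sibling replicate 2. Adjusted over the list alone, 2 S phase genes were higher and 1 lower, 8 inflammation genes were lower, 1 exocrine pancreas gene was lower, and 1 mitochondrial gene passed in each direction. Leaving out sibling replicate 2 raised the S phase genes that rose to 8, and 0 rose when any of the other libraries was left out. The other lists kept their counts of higher and lower genes when adjusted over the list alone.

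The unfolded protein response and amino acid stress list fell in 11 of 29 tested genes and rose in 4, with a median of -1.68 (camera adjusted p = 0.0136; adjusted p = 0.558 with an estimated correlation). The list took 0.168% and 0.181% of gene reads in the mutants, 0.136% in sibling replicate 1 and 0.423% in sibling replicate 2. Sibling replicate 2 also held nearly all exocrine pancreas reads. With total-count scaling 8 of the 29 rose and 3 fell (median 0.06), and with ribosomal protein scaling 14 rose and 2 fell (median 1.03). The number that fell was 2 without mutant replicate 1, 5 without mutant replicate 2 and 20 without sibling replicate 1. The stress gene nupr1b, the serine metabolism enzyme SHMT2 and EDEM1 fell, at -5.26 ± 0.47, -3.12 ± 0.36 and -2.39 ± 0.37, and EDEM1 was at 0.29 with ribosomal protein scaling. Of 9 sterol genes 6 fell and 2 rose, with a median of -2.98 (camera adjusted p = 0.0624), and with ribosomal protein scaling 3 fell and 3 rose. The sterol regulator insig1, STARD4 and ACAT2 fell, at -5.55 ± 0.44, -4.47 ± 0.56 and -4.10 ± 0.57. Of 13 mitochondrially encoded genes 4 rose and 2 fell (median 0.47, camera adjusted p = 0.83), against 10 and 0 with total-count scaling and 13 and 0 with ribosomal protein scaling. MT-ND2 rose by 1.44 ± 0.33 and MT-ND5 by 0.91 ± 0.34, and MT-ND3 fell by 1.61 ± 0.34 but was at 0.05 with total-count scaling. Mitochondrial calls numbered 0 without either mutant library, 9 rose and 1 fell without sibling replicate 1, and 3 rose and 5 fell without sibling replicate 2. For sterol genes 0 rose whichever library was left out, and 3 fell without mutant replicate 1. Germline genes had 57 and 40 reads in the mutants and 21 and 20 in the siblings, and 0 passed the count filter. In all, 7 lists were higher and 5 lower of 21 tested by camera, and 0 passed with an estimated correlation. By fry 12 passed, but these were not the same lists. Exocrine pancreas and the unfolded protein response did not pass (fry adjusted p = 0.068 and 0.121). Inflammation and sterol genes passed by fry only (fry adjusted p = 0.039 and 0.0046).

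Reads on repeats were higher in the mutant libraries, and LTR retrotransposons had the highest median of the 7 classes tested. Repeat reads per gene read were 16.9 and 18.7 in the mutants and 3.44 and 1.98 in the siblings. Against raw gene reads the means were 17.8 ± 1.26 and 2.71 ± 1.03 (SD, n = 2), a 6.56-fold difference. Against scaled gene reads the folds in summed class CPM were smaller. Among classes with reads in the siblings they ran from 1.06 for structural RNAs to 3.97 for LTR. Simple repeats were at 1.66 and DNA transposons, the class with the most reads, at 2.49. The size of the difference thus depends on the gene scaling. The nuclear RNA malat1, named after its values were seen, took 1.11% and 1.13% of gene reads in the mutants and 0.204% and 0.105% in the siblings. Scaled to gene counts, 2583 of 3366 tested repeat families were higher and 143 lower, with a median log2 fold change of 1.98 (edgeR quasi-likelihood test, Benjamini-Hochberg). Scaled to the repeat counts themselves, 392 of 3313 were higher and 508 lower. In that scaling the split was 100 and 249 without mutant replicate 1, 93 and 243 without mutant replicate 2, 826 and 792 without sibling replicate 1, and 966 and 785 without sibling replicate 2. Scaled to gene plus repeat counts, 1756 were higher and 243 lower. Without mutant replicate 1 the gene-scaled test gave 1464 changed families and without mutant replicate 2 it gave 1354.

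Of 487 tested LTR families 421 rose and 7 fell, with a median of 2.38, and 107 were at least 10-fold higher. The endogenous retrovirus ERV1-N5-I_DR had 116541 and 78126 reads in the mutants and 276 and 171 in the siblings, a rise of 7.43 ± 0.41 (edgeR, Benjamini-Hochberg adjusted p = 1.64e-06). Gypsy134-I_DR rose by 6.62 ± 0.43, and Gypsy73-I_DR, at 0 in both siblings, was at least 67.0-fold higher. Of 78 LINE families 73 rose and 0 fell, with a median of 2.03, among them CR1-37_DR by 3.23 ± 0.30 and L1-3_DR by 4.47 ± 0.44. Of 403 DNA transposon families 366 rose and 5 fell, with a median of 1.76. Polinton-2_DR rose by 6.96 ± 0.49, while DNA-8-5_DR had 10862 and 11950 reads in mutants against 89210 and 78283 in siblings and fell by 4.22 ± 0.28. With scaling to repeat counts the LTR median was 0.63, with 117 families higher and 38 lower. The LINE median was also positive, at 0.28, with 17 higher and 11 lower. The DNA median was -0.01, with 56 higher and 97 lower.

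All 15 satellite families rose, with a median of 1.47, including SAT-1_DR by 5.74 ± 0.41 and Sat-5_DR by 3.86 ± 0.41, and the median was -0.23 with scaling to repeat counts. Of 2295 simple repeats 1646 rose and 127 fell, with a median of 1.98. Among structural RNAs 29 of 55 rose and 4 fell, with a median of 1.19 that was -0.65 with scaling to repeat counts. The small nucleolar RNA U3 fell by 2.65 ± 0.26, and was at 0.003 with ribosomal protein scaling. All 13 unclassified families rose, with a median of 1.89. Against the other families, camera placed DNA, LINE and LTR families higher (adjusted p = 0.00207, 0.00454 and 0.0349). It placed simple repeats and structural RNAs lower (adjusted p = 0.00207 and 0.00454), although their medians were positive. The DNA median, 1.76, lay below that of all families and that of simple repeats, both 1.98, so the camera directions do not follow the medians. None of the 5 classes passed with an estimated correlation (adjusted p = 0.758 for the 3 placed higher and 0.56 for the 2 placed lower). Fry called all 7 classes higher. Without mutant replicate 1 camera called 0 classes, without mutant replicate 2 it called 1, and without sibling replicate 2 it called 2.

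**Figure D3:**
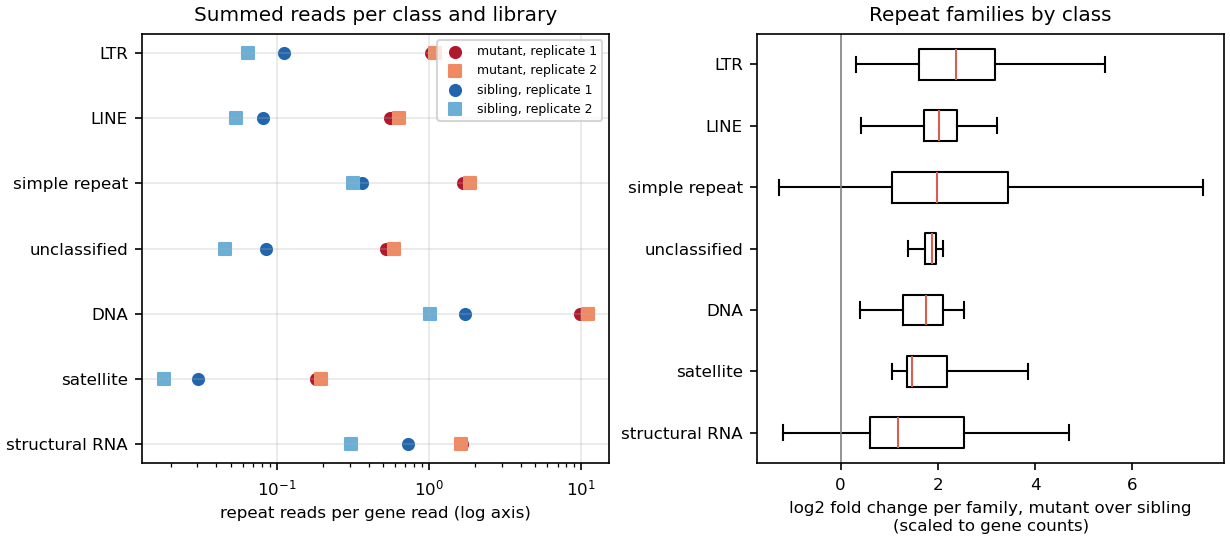
Left, repeat reads per gene read of each class on a log axis, with 1 point per library (red mutants, blue siblings). Right, log2 fold change per tested family scaled to gene counts, as boxes of the quartiles with a red median and whiskers from percentile 5 to percentile 95; the LTR median is 2.38, and the DNA, satellite and structural RNA medians turn negative when scaled to repeat counts.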

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

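Most named genes and lists kept their direction and side of the threshold: 770 gene values, 165 list values and 331 repeat values did so, while 122, 4 and 4 lost the threshold and 13 list values gained it. Of the repeat class values 20 kept both, 17 lost the threshold, 2 gained it and 3 turned direction. The scalings of genes named after their values were seen, repeat scaling with libraries left out, ribosomal protein scaling, total-count scaling of the lists, and the leave-one-out values of the ratio of repeat to gene reads were added after seeing the data. Changed genes numbered 3002 with no count filter and 2232 with at least 1 CPM in 2 libraries, where more low-count genes are tested. Genes higher in mutants numbered 5585 (total counts), 1540 (no filter), 1065 (1 CPM), 1706 (DESeq2) and 6444 (ribosomal protein scaling), and lower genes 1015 (total counts), 1167 (1 CPM) and 650 (ribosomal protein scaling). Leaving out each library gave 1264 to 4632 changed genes, 340 to 2405 higher and 924 to 2227 lower. With an estimated correlation 0 lists and 0 classes passed.

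Repeat families changed in 900 cases scaled to repeat counts, 392 higher and 508 lower. Higher families numbered 3986 with ribosomal protein scaling, and lower families 30 (total counts), 88 (no filter), 88 (1 CPM), 17 (ribosomal protein scaling) and 243 (gene plus repeat counts). Leaving out each library gave 1354 to 3183 changed families, 1299 to 3028 higher, 52 to 183 lower and 0 to 5 classes, and the fold in repeat reads per gene read, mutant over sibling, was 5.18 to 8.97. Scaled to repeat counts 1 class passed.

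Over the members tested with all libraries, directions turned as follows, and the cause was not tested. With ribosomal protein scaling the medians were 0.39 for inflammation, 1.41 for intestine and 1.03 for the unfolded protein response, and CCNG1 was at 0.39, rps27l at 0.54, EDEM1 at 0.29, MT-ND3 at 0.99, U3 at 0.0032, apoeb at 1.57, krt8 at 0.17 and krt92 at 0.61, and trim25 was higher (adjusted p = 0.0144). With total counts intestine was at 0.46, the unfolded protein response at 0.058, MT-ND3 at 0.046, trim25 at 0.55 and apoeb at 0.63. Leaving out each library put mitosis between -0.63 (without sibling replicate 1) and 2.31. Over all members that pass the count filter of each such fit, the islet median ran from -6.02 to 7.31 and the macrophage and neutrophil median from -0.38 to 0.57, where other members are tested. Scaled to repeat counts DNA families were at -0.0064, satellites at -0.23 and structural RNAs at -0.65.

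With the replicate number as a block, 4569 genes, 2219 repeat families, 13 lists and 4 classes changed. Deviations of libraries with the same number correlated at 0.0425 over genes and -0.0198 over repeats. With a single difference per group, these values cannot show whether equal numbers mark the same clutch. At this depth and with 2 libraries per group, a 2-fold change was recovered for 2.47% of simulated genes, drawn with a single dispersion for all genes.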

Other observations

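Several gene families, chosen after their values were seen, moved together. Collagen genes were higher in mutants in 31 of 35 tested and lower in 0, with a median log2 fold change of 4.42 (6.11 with total-count scaling), and protocadherins, adhesion proteins of neurons, were higher in 19 of 20 with a median of 5.58. Some members of both families, such as PCDH19 and COL11A1, had 0 reads in both siblings, so their fitted folds depend on the prior count. Reads were found for 45 hox genes in the mutant libraries and 9 in the sibling libraries. Cytochrome P450 genes were lower in 28 of 29 and apolipoproteins in 11 of 14, with medians of -4.91 and -5.14. Ribosomal protein genes were lower in 79 of 79 with a median of -2.67, or -0.93 with total-count scaling, and scaling to these genes themselves sets the median near 0.

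The most abundant liver transcripts made up much of the sibling libraries. The apolipoprotein apoa2 had 40675 and 48187 reads in siblings and 165 and 93 in mutants, and the transferrin tfa had 19982 and 27405 against 91 and 58. The muscle actin actc1b had 42 and 22 reads in siblings and 5822 and 5029 in mutants. Insulin had 0 and 102 reads and the haem enzyme alas2 had 34 and 2765 reads in sibling replicates 1 and 2.

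All tests in the following paragraphs were chosen after the results were seen. All of them were also rewritten after a first run. A test of liver tissue in the sibling libraries, in which the lowest of the 6 tissue list medians lay 2.65 above the median of all genes, restated the pattern and was dropped. The spread of repeat classes was first taken over DNA, LINE, LTR and simple repeats alone, at 0.62, which had favoured a general excess. The ratio for LTR families was first judged without leaving out libraries. In the first run dilution was judged on all 6 lists at once against the mean of the siblings, with a smallest ratio of 2.57, which counted against dilution for skin as well. The interferon list was at first set against the lowest of the 6 tissue lists, a difference of -1.05, in a form that left the question open whatever the outcome. The minimum of 10 tested members in the rewritten interferon test was set when it was known that 5 macrophage and neutrophil genes had been tested, so that its outcome was fixed beforehand.

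Marker lists of muscle, eye, nerve, cartilage and skin took lower shares of reads in the libraries labelled sibling, although 3 skin keratins were higher there with TMM scaling. Loss of abundant liver and pancreas transcripts in the mutants alone would raise all other shares by a common factor. It was estimated from the share of reads outside all genes called lower, and was 2.79 on average. That share was 80.3% and 79.8% in the mutants and 20.3% and 37.0% in the siblings. The genes called lower included 79 ribosomal protein genes but not 9 of the 11 tested exocrine markers. Most pancreas reads of sibling replicate 2 therefore counted as other reads. For 5 of the 6 lists the rise in share exceeded that factor by at least 5.93 times against either sibling library, which argues against this explanation. For skin the ratio was 1.45 against sibling replicate 1 and 4.47 against sibling replicate 2. The latter depends on counting pancreas reads as other reads, so for skin the explanation cannot be told apart from others. Whole larvae would hold eye and nerve tissue, as the mutant libraries did. The sibling libraries held 3 and 4 lens reads, 9 and 8 neuronal reads and 18 and 19 photoreceptor reads. Hepatocyte markers took 19.9% and 15.7% of their gene reads. These values argue against whole larvae as the source of the sibling libraries, despite the labels. Mostly liver and neighbouring digestive tissue would give such values, although tissue origin was not tested. An effect of the mutation on liver or pancreas stays open, because tissue makeup and genotype coincide in this design.

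Repeat reads per gene read were higher in the mutants. A general excess of reads outside gene annotation might raise all classes by the same factor. The medians of the 7 tested classes lay within 1.19 of each other. This was between the limits of 1 and 2 set for and against an equal rise, so an equal rise stays open on the medians. That explanation forbids an excess of LTR families once repeats are scaled to their own counts, but 117 were higher and 38 lower there, a ratio of 3.08, and leaving out each library gave ratios of 2.12 to 3.53. Against the other classes, with 275 higher and 470 lower, Fisher's exact test gave an odds ratio of 5.25 (two-sided p = 1.14e-18), over families that are not independent replicates. Most of these other families were simple repeats, with 193 higher and 341 lower. The odds ratio was 2.25 without sibling replicate 2, where the other classes had 761 higher and 701 lower, 8.11 without mutant replicate 2 and 9.23 without mutant replicate 1. The LTR median was 0.63 and that of the other families 0.085 with all libraries, but 0.57 and 0.43 without sibling replicate 2. The LTR values count only against an equal rise. An excess that adds reads in other proportions could give larger folds to families with few sibling reads, and was not tested. Whether the LTR excess follows the mutation or the tissue makeup of the libraries was not tested.

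Interferon and antiviral genes were higher in the mutants. If cells missing from the sibling libraries were the source, immune cell markers might rise by as much, and the macrophage and neutrophil median lay 0.092 below the interferon median. Leaving out each library put the immune median between -0.38 and 0.57, which was 1.63 to 2.13 below the interferon median. Those fits tested 7 to 9 immune genes against 5 with all libraries, so the medians cover different members. With so few immune genes that went both ways, an effect of the mutation and a difference in cell makeup cannot be told apart.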
